A study of Mus musculus with 6 samples.

How the data were processed

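Total RNA from the aorta of mice was sequenced in 6 libraries, 2 in each of 3 groups. The groups were C57BL/6J mice on chow, ApoE-/- mice on chow, and ApoE-/- mice put on a high-fat diet at 3 months of age for 3 months, the regimen that gives these animals atherosclerosis. Mice without apolipoprotein E clear cholesterol-rich lipoproteins poorly. Libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols, and no strand setting is given in the sources used here. A circRNA is a transcript whose ends are joined by back-splicing, and a read across that join (a junction read) is its direct evidence.

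The deposited tables list circRNAs by chromosome, start and end on GRCm38 (mm10), with a host gene symbol. Per the file headers, each library has a count column, an RPM column and a junction column. The deposited junction values are whole-number counts of reads across the back-splice join. The deposited count column holds whole-number counts of the reads assigned to the whole circRNA interval, junction reads included; linear transcripts and introns in the interval contribute to it. The deposited RPM column is that count scaled to the library's total, so each library's total could be computed from the 2 columns, and it came to between 69130844 and 77352690 reads. TopHat and HTSeq are named in the submitters' processing notes, without versions. The program that called back-splice joins is not given in the sources used here. Of the 5676 circRNAs whose interval lies wholly under other listed intervals, 87.9% had no read besides junction reads, against 0.128% of the 10917 that lie under no other listed interval, so reads shared by overlapping intervals appear to have been left out. The tables held 20532 circRNAs and 7051 host symbols. Of these symbols 6220 are in the RefSeq gene table of GRCm38.p6 and 365 more matched by a synonym. No symbol is given for 2133 circRNAs, which entered the circRNA tests but no host-gene sum. The RefSeq table holds gene bounds and no exons, so exon or intron positions were not analysed here.

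The labels put the libraries in the groups. The columns in the file of the library labelled ApoE-/- chow 1 are named for a C57BL/6J sample, 1 such conflict among the 6 libraries. The label was kept, and results without this library are given. Both ApoE-/- chow libraries carry sample numbers far from those of the other groups, and no age of the chow groups was available here. Diet and genotype can therefore not be told apart from a batch or an age difference. Replicates carry numbers in the labels, and nothing says that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

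Before the data were examined, 3 pairwise comparisons and the contrast of the high-fat group with both chow groups were fixed, with the tests, the gene lists, the rule for named genes and most alternatives. Junction reads per circRNA, and summed per host gene, were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, TMM scaling). A circRNA or host gene was tested with at least 5 junction reads in at least 2 of the 6 libraries. All libraries shared 1 estimate of the spread, with 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A further measure was chosen after the data were seen: the interval count minus the junction reads, summed per host gene, with at least 10 reads in 2 libraries. These interval reads mix linear, intronic and circular RNA of the listed part of a gene, and without strand they can include an antisense neighbour. They are not a gene-expression measure of the whole gene. A standard error is the log2 fold change divided by the root of the test's F value. A fold against a group with 0 reads was computed against a floor of 3 reads per library and is a lower bound; intervals and floors cover counting error only.

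Gene lists were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 between genes and again with an estimated correlation, for lists with at least 3 tested members. The 20 lists were smooth muscle, macrophage and myeloid, lymphocyte, endothelial, fibroblast, adipocyte, striated muscle, Schwann and neural, blood cell, extracellular matrix, cholesterol and lipid, inflammation signalling, TGF-beta, Wnt and Notch signalling, endoplasmic reticulum stress and autophagy, cell cycle, chromatin modifiers, back-splicing regulators, widely reported circRNA hosts, Y-linked and X-inactivation genes. Of these, 16 could be tested by junction reads and 18 by interval reads.

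The named circRNAs of each comparison are those past the threshold whose groups do not overlap, up to 10 per direction by fold and 2 per host gene. Where fewer than 5 passed, those with the smallest unadjusted p fill up to 5 and are given as not passing. From each list up to 4 members with the highest level may be named, plus any that pass. The 10 most abundant circRNAs, Apoe, and the most abundant circRNA of Esyt2, Map3k5, Lrp6, Hipk3 and Zfp609 complete the rule, which was also applied to host genes. The other host gene counted as higher against both chow groups, which the rule also names, is not reported here.

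Alternatives were DESeq2 1.42.0, DESeq2 size factors, scaling to each library's total of the tested reads without TMM (total-read scaling), lower and higher read minimums, a threshold of 0.1, the replicate number as a block, only the 4 libraries compared, and each library left out. For interval reads, the total in total-read scaling holds Rpph1, Rmrp and Rn45s, which made up 27.0 to 67.8% of interval reads by library. Alternatives added after the data were seen were the count column, omission of circRNAs with a doubtful junction zero, omission of 2 libraries together, and all those of the interval reads. Library counts were compared by exact permutation tests, after thinning to 3706 junction reads as well (mean of 20 draws). The interval of the median ratio at junction zeros came from 2000 bootstrap draws of host genes. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

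The tests were tried on simulated counts with 200 changed genes per level, 50 at each fold, drawn from the real means, spreads and library sizes. For the high-fat diet comparison, 16% of 16-fold changes and 0% of 4-fold changes were recovered among 1015 circRNAs, and 28% and 2% among 1262 host genes. Interval reads of 6122 host genes recovered 84% of 16-fold, 42% of 4-fold and 4% of 2-fold changes. False calls numbered 1, 0 and 6 at these levels. A list of 41 extracellular matrix genes raised 2-fold by interval reads was recovered (camera in limma, adjusted p = 3.6e-21, or adjusted p = 0.0338 with an estimated correlation), with 1 other list called. A 2-fold rise of 25 chromatin modifiers by junction reads was not recovered (camera in limma, adjusted p = 0.206). The simulated genes varied independently, while the matrix list had an estimated correlation of 0.231 in the real diet comparison by interval reads. These trials therefore do not show how the preset correlation behaves where genes vary together.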

Results

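Back-spliced RNA was counted in aortae of C57BL/6J mice on chow, ApoE-/- mice on chow and ApoE-/- mice on a high-fat diet, with 2 libraries per group. The series asks which circRNAs differ in the atherosclerotic aorta from those of both chow-fed control groups. The libraries held 71809199 and 69130844 reads in the C57BL/6J group, 77352690 and 75452177 in the ApoE-/- chow group, and 76355980 and 76578908 in the high-fat group. Junction reads were few and uneven: 26605 and 3706 in C57BL/6J 1 and 2, 14575 and 14519 in ApoE-/- chow 1 and 2, and 34805 and 16511 in high-fat 1 and 2. Scaled to the library totals this gave 212 ± 224 RPM in C57BL/6J, 190 ± 2.83 RPM in ApoE-/- chow and 336 ± 170 RPM in high-fat aortae (SD, n = 2 each). The low yield of C57BL/6J 2, 53.6 RPM against 370 RPM in C57BL/6J 1, enters every comparison with wild type.

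**Figure D1:**
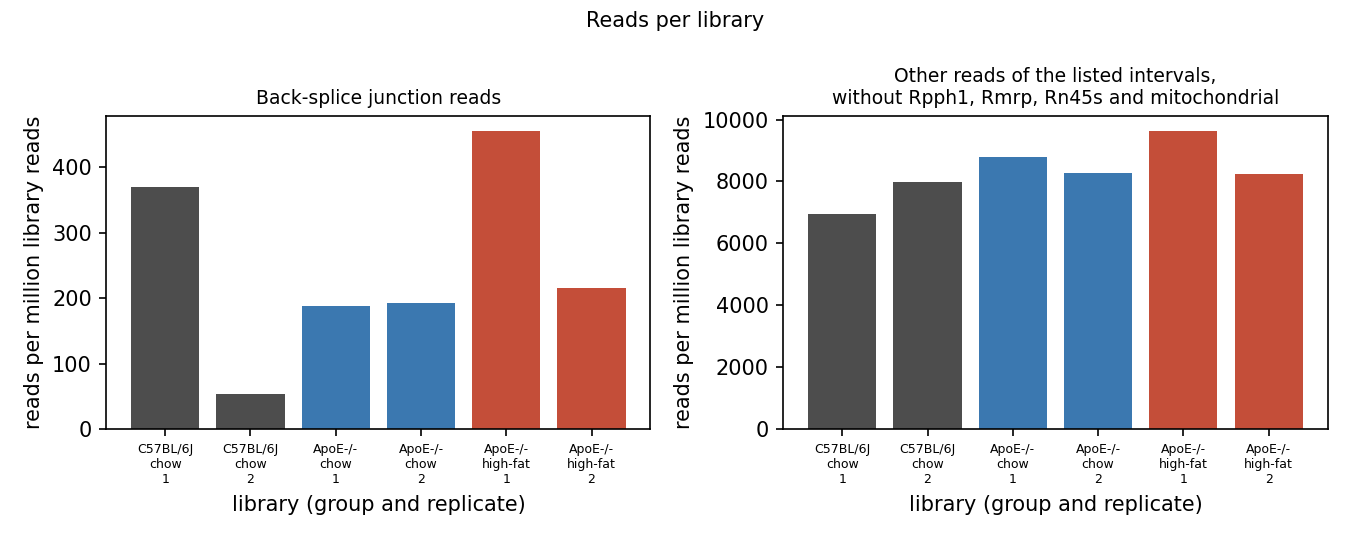
Bars give each library's junction reads (one panel) and other interval reads without Rpph1, Rmrp, Rn45s and mitochondrial intervals (the other panel), both scaled to the library total in RPM, for the 6 libraries coloured by group. Junction reads range from 53.6 to 456, while the other interval reads range from 6950 to 9635.

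Most circRNAs were seen in a single library. Of 20532 listed circRNAs, 16521 (80.5%) had a junction read in exactly 1 library and 189 (0.921%) in all 6. Their genomic spans ran from 56 to 99202 bp with a median of 1822.5 bp. High-fat libraries held a mean of 6680 circRNAs with a junction read, against 3834.5 in ApoE-/- chow and 3641 in C57BL/6J libraries. The ratio of the high-fat mean to that of both chow groups was 1.79 (exact two-sided permutation p = 0.2; the smallest possible is 0.0667). After thinning all libraries to 3706 junction reads it was 1.11 (exact two-sided permutation p = 0.133). The unthinned ratio lay between 1.19 and 2.38 when 1 library was left out, the lowest without high-fat 1 and the highest without high-fat 2.

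The most abundant circRNA came from Nfix, a nuclear factor I transcription factor, at chromosome 8, 84771784 to 84772315 (532 bp, inside the gene), with 1908 ± 607 of every 100000 junction reads (SD, n = 6). Next were circRNAs of Elf2, an ETS-family transcription factor (741 ± 303), Arhgap32 (666 ± 193), and Pcdh7, a protocadherin (502 ± 459, with 0 reads in C57BL/6J 2 and ApoE-/- chow 2). Arhgap32 was above Elf2 in C57BL/6J (656 against 593) and ApoE-/- chow (708 against 578) and below it in high-fat libraries (633 against 1053). Rnf169, Tasp1, Pdlim5, Ogdh, Papd7 and Rad52 followed with 447, 443, 413, 396, 390 and 364. This order is not that of each group: in C57BL/6J Pdlim5 (473) and Rnf169 (467) were above Pcdh7 (436), and Rad52 was at 436 in C57BL/6J, 444 in ApoE-/- chow and 213 ± 301 in high-fat libraries. None of these 10 passed in any comparison (edgeR). Of the 5 hosts named in advance, the circRNA of Lrp6, a Wnt co-receptor, had 12 and 7 reads in C57BL/6J, 11 and 8 in ApoE-/- chow and 58 and 17 in high-fat libraries. That of Zfp609 had 7 and 0, 5 and 7, and 5 and 9 reads in the same order, Map3k5 27 and 4, 0 and 5, and 9 and 5, and Hipk3 31 and 0, 0 and 0, and 0 and 10. The Esyt2 circRNA had 186 of its reads in high-fat 1.

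The diet comparison asks what a high-fat diet changed in ApoE-/- aortae. The ApoE-/- chow libraries were numbered apart from the high-fat ones, so diet cannot be told apart from a batch or an age difference. A circRNA of Tlk1, a kinase of chromatin assembly, fell. It spans chromosome 2, 70768862 to 70786995 (18134 bp, inside the gene at 70712407 to 70825816), and had 48 and 65 junction reads in ApoE-/- chow and 0 in both high-fat libraries. That is at least 26.4-fold lower, and it was the only one of 1015 circRNAs to pass (edgeR, adjusted p = 0.00049). C57BL/6J libraries had 0 and 18 reads, and all junction reads of Tlk1 together were 55 and 70 in ApoE-/- chow against 22 and 9 in high-fat libraries (log2 -2.76 ± 0.81 SE; edgeR, adjusted p = 0.274; it passed with total-read scaling and without C57BL/6J 2). The 55 and 70 reads of Tlk1 include the 48 and 65 of the called circRNA, so the host total is no separate support. The other Tlk1 junction reads were fewer in ApoE-/- chow than in high-fat libraries. A circRNA of Eefsec, the selenocysteine elongation factor, had 29 and 13 reads against 0 and 0 (at least 9.84-fold lower) and did not pass (edgeR, adjusted p = 0.0769). It passed in place of Tlk1 with total-read scaling (edgeR, adjusted p = 0.0181), which moved the median log2 of all circRNAs by -0.12, and beside Tlk1 without C57BL/6J 2 (edgeR, adjusted p = 0.0498; 2 circRNAs passed).

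Across alternatives the edgeR or DESeq2 adjusted p of the Tlk1 circRNA ran from 8.2e-10 to 1. It did not pass with DESeq2 (adjusted p = 0.424), DESeq2 size factors (edgeR, adjusted p = 0.169), a minimum of 10 reads or total-read scaling (edgeR, adjusted p = 0.999 each), the count column (edgeR, adjusted p = 0.327), or without high-fat 1 (edgeR, adjusted p = 1) or high-fat 2 (edgeR, adjusted p = 0.0638). Apart from the count column and the left-out libraries, these settings use the same 48 and 65 reads against 0 and 0. Total-read scaling brought the median log2 of all circRNAs nearer 0, from 0.19 with TMM to 0.07. Without ApoE-/- chow 1, 3 circRNAs passed, Tlk1 among them.

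Other circRNAs had reads in one diet group alone without passing (edgeR, adjusted p = 0.705 each). The Zfp426 circRNA had 42 and 0 reads in high-fat and 0 in ApoE-/- chow libraries, so its 3.38-fold value rests on high-fat 1 alone. The circRNAs of Bckdhb, a branched-chain amino acid enzyme (37 and 9 reads), Ralgps2 (27 and 12) and Prr5l (18 and 15) were higher. Their folds were at least 4.39, 4.05 and 3.80, each with 0 reads in ApoE-/- chow. Those of Dmd (dystrophin), Ezh2 (the histone H3K27 methyltransferase) and Pdlim5 (a Z-disc adaptor) had 0 reads in high-fat libraries and 17 and 6, 0 and 22, and 0 and 19 in ApoE-/- chow. DESeq2 called 0 circRNAs, and 54 of the 1015 had an unadjusted edgeR p under 0.05 where chance gives 50.75. The groups did not overlap for 34.4% of circRNAs. Chance gives 33.3% only where no counts are tied. A circRNA with 0 reads in a library of each group cannot separate them, so the chance share here is lower. How much lower was not computed, so the 34.4% cannot be judged against chance.

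**Figure D2:**
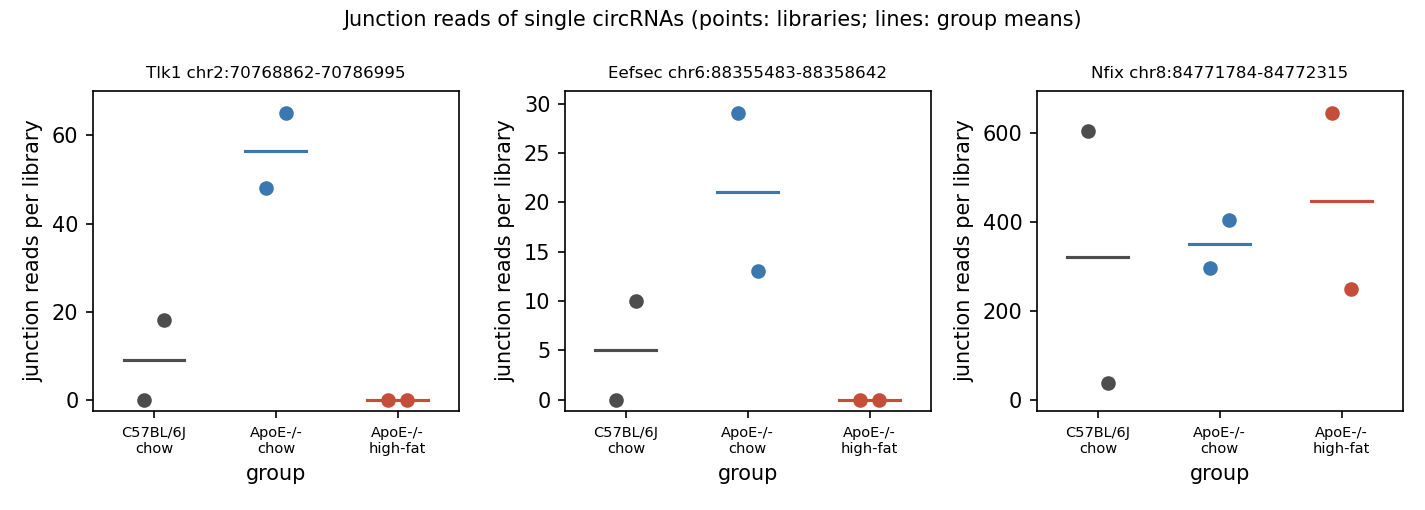
Points give the junction reads per library of circRNAs of Tlk1, Eefsec and Nfix in the 3 groups, and lines the group means. The Tlk1 circRNA has 48 and 65 reads in ApoE-/- chow and 0 in high-fat libraries, the Eefsec circRNA 29 and 13 against 0, and the Nfix circRNA reads in all 6 libraries.

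Summed per host gene, junction reads of Gigyf2, a translational repressor, fell on the high-fat diet by 3.96 on the log2 scale (SE 0.85; edgeR, adjusted p = 0.0054), the only one of 1262 host genes. This rested on 195 reads in ApoE-/- chow 1 against 5 in ApoE-/- chow 2, 15 and 6 in high-fat libraries; without ApoE-/- chow 1 the log2 change was 0.28 (edgeR, adjusted p = 0.994). Hosts with no junction read in ApoE-/- chow were Hip1, a clathrin adaptor (34 and 11 reads in high-fat), and Trpc6, a calcium-permeable channel (37 and 12), neither of which passed (edgeR, adjusted p = 0.369 each). Gigyf2 was also lost without each other library except ApoE-/- chow 2 (edgeR, adjusted p from 0.468 to 1.00), with DESeq2, with a minimum of 10 reads and with no read minimum. DESeq2 called 0 host genes, and 55 had an unadjusted edgeR p under 0.05 where chance gives 63.1.

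The remaining reads of the circRNA intervals gave more counts per gene. Ppbp, a platelet chemokine, was at 62.7 ± 22.5 CPM in high-fat and 8.65 ± 1.49 CPM in ApoE-/- chow aortae (SD, n = 2; log2 2.84 ± 0.55 SE), and Trpc6 at 99.4 ± 11 and 18.6 ± 2.03 CPM (log2 2.41 ± 0.49 SE). Neither passed (edgeR, adjusted p = 0.0755 each). Both passed with DESeq2 (adjusted p = 0.0359 each), a minimum of 20 reads (edgeR, adjusted p = 0.0465), the 4 libraries alone (edgeR, adjusted p = 0.00669), without C57BL/6J 1 (edgeR, adjusted p = 0.00257) and without C57BL/6J 2 (edgeR, adjusted p = 0.00506). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, was at 207 ± 45.7 against 58.4 ± 38.7 CPM (log2 1.82 ± 0.52 SE) and passed only without C57BL/6J 1 (edgeR, adjusted p = 0.0471). The 2 intervals with the deposited symbol Lyz1 lie between 117277466 and 117289706 on chromosome 10, and whether they take in its copy Lyz2 was not checked. Thbs1, a matrix glycoprotein, stood at 241 against 72.4 CPM and Lyz1, a lysozyme whose copy Lyz2 is nearly identical, at 387 ± 60.8 against 139 ± 33.9 CPM. Neither passed (edgeR, adjusted p = 0.999 each), but both did without C57BL/6J 1 (edgeR, adjusted p = 0.0248 and 0.0228) or C57BL/6J 2 (edgeR, adjusted p = 0.028 each), and Lyz1 with the 4 libraries alone (edgeR, adjusted p = 0.047). Uri1 (log2 -1.72), Syap1 (-2.93), Elovl5 (-4.08), Zfp949 (-1.72) and Gli2 (-2.07) had the lowest unadjusted p among genes lower on the diet and did not pass. Of 6122 host genes 0 passed in edgeR and 2 in DESeq2, and 125 had an unadjusted edgeR p under 0.05 where chance gives 306.1; without C57BL/6J 1, 5 passed in edgeR and without C57BL/6J 2, 4.

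No gene list passed for the diet with all libraries, while 4 passed by interval reads without high-fat 1, 2 without C57BL/6J 1 and 1 each without C57BL/6J 2 or ApoE-/- chow 2 (camera in limma). By interval reads, extracellular matrix genes came closest (31 of 41 higher, camera in limma, adjusted p = 0.209). Col3a1 stood at 2980 against 2118 CPM and Fn1 (fibronectin) at 2929 ± 1626 against 2008 ± 56.3 CPM (SD, n = 2 each). For Fn1, high-fat 1 (1779 CPM) lay below both ApoE-/- chow libraries (1968 and 2047 CPM), and high-fat 2 stood at 4079 CPM. Fibroblast genes (18 of 24 higher) and TGF-beta, Wnt and Notch genes (22 of 30 higher) each had a camera adjusted p of 0.228 in limma, and adipocyte (9 of 30 higher) and endothelial genes (5 of 25 higher) 0.286 each. Chromatin modifiers followed (25 of 41; camera in limma, adjusted p = 0.511), then smooth muscle (24 of 38) and blood cell genes (4 of 9; camera in limma, adjusted p = 0.565 each) and lymphocyte genes (3 of 10; camera in limma, adjusted p = 0.566). The camera adjusted p in limma was 0.753 for cell cycle (11 of 21 higher), cholesterol and lipid (14 of 26), endoplasmic reticulum stress and autophagy (17 of 28), macrophage and myeloid (13 of 24), Schwann and neural (3 of 7), striated muscle (4 of 11) and widely reported circRNA host genes (30 of 54). It was 0.788 for back-splicing regulators (14 of 23) and 0.790 for inflammation signalling (13 of 22). Blood cell genes had a median log2 of -0.02 and a mean of 0.27, cell cycle genes 0.19 and -0.02, and Schwann and neural genes -0.03 and 0.04 with a downward test. By junction reads the smallest adjusted p was 0.379 for endothelial hosts (4 of 6 higher; camera in limma). Adjusted over the list alone, Ppbp and Gpnmb passed by interval reads, 2 members against 0 over all genes, and by junction reads Gigyf2 passed both ways. The Y-linked genes Uty and Eif2s3y had interval reads in all 6 libraries (12.3 and 10.8 CPM in high-fat, 9.66 and 10.5 CPM in ApoE-/- chow aortae), and of the X-inactivation genes Ftx was at 11.5 and 5.46 CPM; both lists were too small to test.

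Atherosclerotic aortae were next set against those of wild-type mice, a comparison in which genotype and diet both differ. Gpnmb rose in interval reads, from 22.6 ± 6.43 CPM in C57BL/6J to 207 ± 45.7 CPM in high-fat aortae (SD, n = 2; log2 3.18 ± 0.56 SE), the only one of 6122 host genes (edgeR, adjusted p = 0.0184). Its intervals lie at chromosome 6, 49042269 to 49045456. Trpc6 (99.4 against 19.1 CPM), Ppbp (62.7 against 10.5 CPM) and Lyz1 (387 against 102 CPM) were higher in each high-fat library than in each C57BL/6J library without passing (edgeR, adjusted p = 0.107, 0.13 and 0.658). All 3 passed without C57BL/6J 1 (edgeR, adjusted p = 0.0047, 0.0257 and 0.000188), and Trpc6 with DESeq2 (adjusted p = 0.0342). Angptl4, an inhibitor of lipoprotein lipase (log2 -1.77), Adamts3, a procollagen protease (-1.72), Ak4, a mitochondrial adenylate kinase (-2.68), Cep89 (-2.12) and Oas1e (-4.58) were lower and did not pass. The Gpnmb call was lost with total-read scaling, which moved the median of all genes by -0.35 (log2 2.70; edgeR, adjusted p = 0.999), and without high-fat 2 (log2 2.94; edgeR, adjusted p = 0.194); without C57BL/6J 1, 158 genes passed. DESeq2 called 2 genes, and 215 had an unadjusted edgeR p under 0.05 (306.1 by chance).

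**Figure D3:**
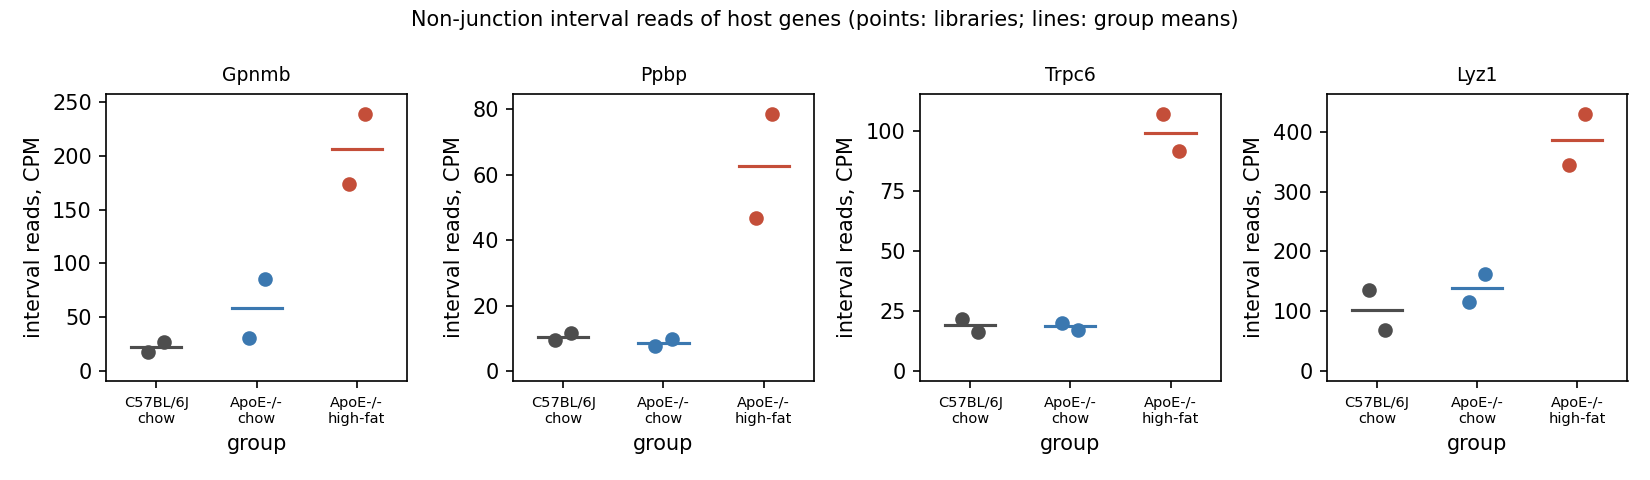
Points give interval reads in CPM of Gpnmb, Ppbp, Trpc6 and Lyz1 in the 6 libraries by group, and lines the group means. Mean Gpnmb was 207 CPM in high-fat, 58.4 CPM in ApoE-/- chow and 22.6 CPM in C57BL/6J aortae, and all 4 genes have their highest mean in the high-fat group.

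By interval reads, smooth muscle genes rose against wild type (28 of 38 higher, mean log2 0.44; camera in limma, adjusted p = 0.00035), and this was lost as an adjusted p = 0.688 with an estimated correlation. Tns1, a focal adhesion protein, stood at 5567 ± 3650 against 2366 ± 1660 CPM (SD, n = 2 each). Its level in high-fat 1 (2986 CPM) lay below that in C57BL/6J 1 (3539 CPM), with high-fat 2 at 8148 and C57BL/6J 2 at 1192 CPM. Flna (filamin A) stood at 5840 against 3773 CPM, Myh11 (smooth muscle myosin) at 3371 against 2199 and Acta2 (smooth muscle actin) at 2863 against 2970. Extracellular matrix genes rose too (28 of 41 higher, mean log2 0.38; camera in limma, adjusted p = 0.000733; adjusted p = 0.688 with an estimated correlation), with Fn1 at 2929 against 1010 CPM, Hspg2 (perlecan) at log2 1.01 and Eln (elastin) at 3311 against 4853 CPM. Adipocyte genes fell (29 of 30 lower, mean log2 -0.26; camera in limma, adjusted p = 0.0242; adjusted p = 0.706 with an estimated correlation), among them Pck1 at log2 -0.63 and Esrrg at -0.57. Macrophage and myeloid genes, the list that holds Gpnmb, were split (12 of 24 higher; camera in limma, adjusted p = 0.891). None of the listed members named here passed alone, Gpnmb excepted. Without C57BL/6J 2 the mean log2 was -0.01 for smooth muscle (camera in limma, adjusted p = 0.989) and 0.05 for matrix genes (camera in limma, adjusted p = 0.841); without high-fat 2 it was 0.25, 0.15 and, for adipocyte genes, -0.11 (camera in limma, adjusted p = 0.354, 0.649 and 0.427). Without C57BL/6J 1 adipocyte genes stood at 0.15 (camera in limma, adjusted p = 0.495), and total-read scaling ended the smooth muscle and matrix calls (camera in limma, adjusted p = 0.205 each). Without high-fat 1, 6 lists passed, and without C57BL/6J 1, 5.

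By junction reads the Tlk1 circRNA was at least 14.5-fold lower than in wild type (edgeR, adjusted p = 0.0074), yet the 18 reads behind this came from C57BL/6J 2 alone, and without that library both groups were at 0 (edgeR, adjusted p = 1). It was the only circRNA called, and it also did not pass without high-fat 1 (edgeR, adjusted p = 1) or high-fat 2 (edgeR, adjusted p = 0.272), with DESeq2, DESeq2 size factors, a minimum of 10 reads, the count column or total-read scaling (edgeR or DESeq2, adjusted p from 0.46 to 1). Those of Cdc14b, a phosphatase (54 and 16 reads in high-fat against 0 and 1), Etv6, an ETS-family repressor (21 and 25 against 0 and 0) and Erbb2ip, a scaffold of ERBB2 (163 and 52 against 35 and 0) were higher, with log2 changes of 4.69 ± 1.67 SE for Cdc14b and 2.41 for Erbb2ip and a bound of at least 2.80-fold for Etv6. Those of Ezh2 (at least 17.7-fold lower; edgeR, adjusted p = 0.124) and Eefsec (at least 8.04-fold lower; edgeR, adjusted p = 0.185) rested on C57BL/6J 2 as well. Among hosts, Phf21a, a component of a histone demethylase complex, had 233 reads in C57BL/6J 1 and at most 10 in any other library (log2 -3.54; edgeR, adjusted p = 0.0839); it passed with total-read scaling and with DESeq2 size factors. Of the host genes 0 passed in edgeR and 0 in DESeq2, which called 0 circRNAs too, and 48 host genes and 47 circRNAs had an unadjusted edgeR p under 0.05 (63.1 and 50.75 by chance). The smallest adjusted p of a junction-read list was 0.865 (camera in limma). Adjusted over the list alone, Ezh2 and Esyt2 passed by junction reads (0 over all genes) and Gpnmb and Ppbp by interval reads (1 over all genes). Host Ezh2 had 0 and 22 reads in C57BL/6J against 7 and 0 in high-fat libraries, and its direction turned without C57BL/6J 2; host Esyt2 had 202 reads in high-fat 1 and 1 in high-fat 2. Total-read scaling moved the median log2 of all circRNAs by -0.28, from 0.46 with TMM to 0.17. That of host genes moved by -0.21, from 0.33 to 0.12. Without ApoE-/- chow 1 or C57BL/6J 2, 2 circRNAs passed; without C57BL/6J 1, 4 host genes, and without ApoE-/- chow 2 or either high-fat library or C57BL/6J 2, 1.

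The genotype comparison asks what loss of ApoE changed on chow, with the same limit of the separately numbered ApoE-/- chow libraries. No circRNA, host gene or interval-read gene passed in edgeR or DESeq2 (0 each); 56 of 1015, 51 of 1262 and 160 of 6122 had an unadjusted edgeR p under 0.05, against 50.75, 63.1 and 306.1 by chance. Without C57BL/6J 1, 65 interval-read genes passed, and without C57BL/6J 2, 4; 1 circRNA passed without ApoE-/- chow 1 and 2 without C57BL/6J 2, and 1 host gene without C57BL/6J 2 or ApoE-/- chow 2 (edgeR). The Apoe interval, chromosome 7, 19696367 to 19696437 inside the gene, was at 76.3 ± 17.1 CPM in ApoE-/- chow and 141 ± 36.7 CPM in C57BL/6J aortae (SD, n = 2; log2 -0.88 ± 0.47 SE), and at 54.7 ± 9.43 CPM in high-fat aortae (log2 -1.37 ± 0.48 SE against C57BL/6J; edgeR, adjusted p = 1.00). It was lower in each of the 4 ApoE-/- libraries than in each C57BL/6J library, and the labels do not say where the targeted sequence lies. Within 10 Mb of Apoe 1 of 75 host genes, Arhgef1, had an unadjusted p under 0.05 by interval reads (1.33%), against 159 of 6046 elsewhere (2.63%; Fisher's exact two-sided p = 1).

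The circRNA of Peli2, a ubiquitin ligase of innate immune signalling, had 16 and 40 reads in ApoE-/- chow and 0 in C57BL/6J libraries (at least 4.65-fold higher; edgeR, adjusted p = 0.409). Those of Cdc14b (29 and 22 against 0 and 1), Magi1, a junctional scaffold (10 and 15 against 0 and 0), Dhrsx (14 and 10 against 0 and 0) and Adrm1 (24 and 0 against 0 and 0) were higher, and those of Atp2a2, the sarcoplasmic calcium pump (0 and 0 against 17 and 8), Nf2 (merlin; 0 and 0 against 27 and 4), Ptpra (0 and 0 against 11 and 6) and Zfp426 (0 and 0 against 30 and 0) were lower, all with an edgeR adjusted p of 0.799. A junction of the mitochondrial chromosome, 12858 to 13109, had 20 and 5 reads in C57BL/6J and 0 in the 4 ApoE-/- libraries. The host H2afy, a histone variant, had 13 and 14 reads in C57BL/6J and 0 in ApoE-/- chow libraries (at least 9.39-fold lower; edgeR, adjusted p = 0.127), and passed with total-read scaling. By interval reads Ubap2 (log2 2.74), Ace, the angiotensin-converting enzyme (1.64 ± 0.53 SE), Barx2 (2.34) and Nov (1.70) were higher and Mcc (-2.44), Klhl12 (-2.52), Megf11 (-2.72) and Ak4 (-2.98) lower without passing.

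Tns1 stood at 3883 against 2366 CPM by interval reads and Acta2 at 2306 against 2970 CPM. For Tns1, ApoE-/- chow 2 (3383 CPM) lay below C57BL/6J 1 (3539 CPM). As a list, smooth muscle genes rose with the genotype (28 of 38 higher, mean log2 0.30). Camera in limma gave an adjusted p of 0.0075, and of 0.997 with an estimated correlation. Without C57BL/6J 2 the mean was -0.12 (camera in limma, adjusted p = 0.577), without ApoE-/- chow 1 it was 0.13 (camera in limma, adjusted p = 0.789), and with total-read scaling the adjusted p was 0.472 (camera in limma); without C57BL/6J 1, 2 lists passed. By junction reads the smallest adjusted p of a list was 0.721 (camera in limma). Gigyf2 alone passed when adjusted over the list alone (0 over all genes), and by interval reads 0 members passed either way. It had 195 and 5 reads in ApoE-/- chow against 13 and 3 in C57BL/6J, and its log2 change of 3.52 turned to -0.73 without ApoE-/- chow 1 (edgeR, adjusted p = 1). Total-read scaling moved the median log2 of circRNAs by -0.19, from 0.19 with TMM to 0.002. That of host genes moved by -0.12, from 0.13 to 0.004.

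Set against both chow groups together, the high-fat aortae had higher interval reads of 3 genes. Ppbp (log2 2.70 ± 0.44 SE) and Trpc6 (2.40 ± 0.39 SE) rose (edgeR, adjusted p = 0.00255 each), as did Gpnmb (2.5 ± 0.42 SE; edgeR, adjusted p = 0.00365), and each was higher in both high-fat libraries than in all 4 chow libraries. The intervals lie at chromosome 5, 90769063 to 90769538 for Ppbp and at chromosome 9, 8609700 to 8680653 for Trpc6. By junction reads 2 host genes rose. Esyt2, a tether of endoplasmic reticulum and plasma membrane, was one (log2 3.74 ± 0.86 SE; edgeR, adjusted p = 0.0192), with 202 of its reads in high-fat 1 and 1 in high-fat 2. It was lost with DESeq2 (adjusted p = 1.00), a minimum of 10 reads, no read minimum, and without ApoE-/- chow 2 (edgeR, adjusted p = 0.208), C57BL/6J 1 (edgeR, adjusted p = 0.595) or C57BL/6J 2 (edgeR, adjusted p = 0.996); without high-fat 1 it had too few reads to be tested. Without C57BL/6J 1, 103 interval-read genes and 5 host genes passed. At the level of single circRNAs 1 was lower, with 3 called without ApoE-/- chow 1 and 0 without high-fat 2 or C57BL/6J 2. DESeq2 called 4 interval-read genes, 0 host genes and 0 circRNAs, and 177, 71 and 64 had an unadjusted edgeR p under 0.05, against 306.1, 63.1 and 50.75 by chance.

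Extracellular matrix (29 of 41 higher; camera in limma, adjusted p = 0.00929) and smooth muscle genes rose (28 of 38; camera in limma, adjusted p = 0.0259) and adipocyte genes fell (25 of 30 lower; camera in limma, adjusted p = 0.0259) against both chow groups. Each had an adjusted p = 0.691 with an estimated correlation. Without high-fat 2 the means were 0.08, 0.10 and -0.03 (camera in limma, adjusted p = 0.984, 0.984 and 0.677). Without C57BL/6J 2 they were 0.13 for matrix and 0.05 for smooth muscle genes (camera in limma, adjusted p = 0.128 and 0.618). The smooth muscle call ended without ApoE-/- chow 2 (camera in limma, adjusted p = 0.374), and the adipocyte call without ApoE-/- chow 1 (-0.04; camera in limma, adjusted p = 0.498) or C57BL/6J 1 (0.01; camera in limma, adjusted p = 0.936). Without high-fat 1, 5 lists passed. By junction reads the smallest adjusted p of a list was 0.921 (camera in limma). Adjusted over the list alone, Hnrpll, Ezh2, whose direction again turned without C57BL/6J 2, and Esyt2 passed by junction reads (1 over all genes) and Ppbp and Gpnmb by interval reads (2 over all genes). Total-read scaling divides by a total that holds the uneven reads of Rpph1, Rmrp and Rn45s. All 3 interval-read calls ended with total-read scaling, which moved the median of all genes by -0.32 (edgeR, adjusted p = 0.999 each) and left log2 changes of 2.06 for Gpnmb, 2.33 for Ppbp and 2.13 for Trpc6. That of Ppbp also ended without high-fat 2 (edgeR, adjusted p = 0.899), Trpc6 without high-fat 1 (edgeR, adjusted p = 0.0872) and Gpnmb without high-fat 2 or ApoE-/- chow 1 (edgeR, adjusted p = 0.257 and 0.263).

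Tlk1 was the 1 circRNA called lower against each chow group, where independent lists of these sizes would share 0.000985 and simulated unchanged groups with the same high-fat libraries shared a mean of 0.06 and at most 1 in 50 draws. The shared number was 2 without ApoE-/- chow 1 and 0 without high-fat 2 or C57BL/6J 2. It stayed at 1 without high-fat 1 and with total-read scaling, but there the circRNA was another, since Tlk1 passed in neither comparison. The number called higher in both was 0, against a simulated mean of 0.1. At an unadjusted edgeR p under 0.05, 16 circRNAs had the same direction in both comparisons, against a simulated mean of 7.34 and a highest of 13. These draws already contain the sharing of the high-fat libraries. They follow a fitted negative binomial spread, which may hold fewer zeros than the real counts (139 zeros against 58 counts of 1 to 3 where at least 10 reads were predicted). The 16 against at most 13 can therefore not be read as a high-fat effect. The excess of Tlk1 over independent lists does not allow for the sharing, so part of it may come from the shared high-fat libraries, which are too few to split.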

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

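Of the tests in this part, that of a shifted junction and that of absent circRNAs were set before their result was seen, and the others, with the reference of the absence test, were chosen only after it.

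C57BL/6J 2 held 53.6 RPM of junction reads, against 188 to 456 RPM in the other 5 libraries. Fewer reads from the listed genes are argued against by its other interval reads, which stood at 0.872 of the mean of the other 5 libraries, and a general failure to call back-splice joins by its junction reads outside annotated genes, at 1.02 of that mean (8.66 RPM; others 5.49 to 15). Within genes the ratio was 0.163 (44.9 RPM; others 183 to 441), which restates the low yield, so fewer circRNA molecules, from the animal or from its preparation, stay open. In this library 61.1% of junction reads came from spans under 2000 bp, against 30.9 to 36.5% in the others, and a loss that acts on longer spans was not tested. Whether the animal or the preparation differed cannot be read from these data, and no biological explanation was tested.

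Several circRNAs had 0 junction reads in a library where the other libraries predicted at least 10, among them the Tlk1 circRNA: 139 of 1475 such values (9.42%), over 113 circRNAs. The ratio of zeros to counts of 1 to 3 was 2.40 (139 against 58). That is above the bound set, after it was seen, against ordinary variation around a level shared by the libraries. The ratio that the fitted spread would give was not computed, so a wide ordinary spread stays open. The prediction pools the other libraries, so an excess in 1 of them gives such zeros too. The Esyt2 circRNA, with 186 reads in high-fat 1 and 0 elsewhere, is a case. The ratio cannot tell a lost circRNA from such an excess. Reads at another listed junction shifted by up to 20 bp were found for a share of 0.00719 of the zeros (1 of 139). How many zeros had such a listed neighbour was not counted, so this share cannot decide on shifted placement. For true absence from the library, a median ratio of interval reads over 0.8 was set as evidence against it, and the ratio was 0.955 in the 40 zeros with enough reads (95% bootstrap interval 0.888 to 1.06). That bound took 1 as the level of a present circRNA, but counted circRNAs had medians of 1.52 in C57BL/6J 1 and 1.28 in high-fat 1, which hold 14 and 13 of these zeros. The medians were 0.815 in high-fat 2 (8 zeros) and 0.770 and 0.744 in ApoE-/- chow 1 and 2 (2 and 3 zeros). Against counted circRNAs of the same library the ratio was 0.830 (0.704 to 0.960), on both sides of the bound. The other 99 zeros had too few interval reads to test. Absence through the animal, loss in the preparation, a filter of the caller, shifted placement, a wide ordinary spread or an excess in another library may each leave such zeros. The called Tlk1 circRNA, like others with 0 reads in 1 group, could be of this kind.

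The library labelled ApoE-/- chow 1 carries column names of a C57BL/6J sample, which could mean a wild-type mouse under a wrong label or a naming slip. A targeted locus often keeps flanking sequence of another strain, so genes near Apoe that separate the other ApoE-/- libraries from wild type were examined within 20 Mb. This library lay on the ApoE-/- side for 12 of 22 of them (54.5%), and for 708 of 1017 elsewhere (69.6%), where 66.7% follows with no genotype effect (one-sided exact Fisher p = 0.956). On the side of the label, its Apoe interval stood at 88.4 CPM, outside the 115 to 167 CPM of the C57BL/6J libraries. Its mitochondrial share was 1.05% of interval and 0.0686% of junction reads, below their 1.77 and 2.07% and 0.756 and 0.823%. Scaled to library totals, however, its mitochondrial interval reads lie between those of the C57BL/6J libraries. Its 10 mitochondrial junction reads stay below their 219 and 28. The flanking genes show no excess that would mark an ApoE-/- mouse, but 22 genes with no detectable genotype effect give little power, the Apoe level rests on 1 interval, and only 2 C57BL/6J libraries set the mitochondrial range, so the label stays open.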

How the results depend on the processing

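Tests chosen only after the data were seen are the count column, the omission of circRNAs with a doubtful junction zero, the omission of C57BL/6J 2 and ApoE-/- chow 1 together, and every alternative of the interval reads. Counts below are in the order diet, against wild type, genotype, against both chow groups, unless named. The reference counts were 1, 1, 0 and 1 circRNAs, 1, 0, 0 and 2 host genes, 0, 1, 0 and 3 interval-read genes, 0, 3, 1 and 3 interval-read lists, and 1 circRNA shared by both high-fat comparisons. At these depths and spreads, 16% of simulated 16-fold changes of 1015 circRNAs passed in the diet comparison. Apart from leave-one-out, counts of calls and the detection ratio moved in 75 cases and stayed in 89; for single genes and lists 14 values reversed, 43 lost and 28 gained a call and 823 did neither. Except where named, the cause was not tested.

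DESeq2 gave 0 circRNAs in the diet, wild-type and both-chow comparisons, 0 host genes for diet and both chow groups, 2 interval-read genes for diet and 2 against wild type, and 0 shared. DESeq2 size factors gave 0 circRNAs in the same 3 comparisons, 1 host gene against wild type and 0 shared. A minimum of 10 reads gave 0 circRNAs in these 3, 0 host genes for diet and both chow groups and 0 shared, and one of 20 gave 2 interval-read genes for diet. With no filter there were 3, 3, 2 and 2 circRNAs, 0 host genes for diet and both chow groups and 2 shared. Omission of circRNAs with a doubtful zero, which takes out Tlk1 by construction, left 0 circRNAs in the 3 comparisons, 0 host genes for diet and both chow groups and 0 shared. The count column gave 0 circRNAs for diet and wild type, 2 for both chow groups and 0 shared. Only the 4 libraries compared gave 0 circRNAs against wild type and 3 interval-read genes for diet. Total-read scaling gave 3, 1, 2 and 4 host genes, 0 interval-read genes against wild type and both chow groups, and 1, 0 and 1 lists against wild type, for genotype and against both chow groups. A threshold of 0.1 gave 2 circRNAs for diet and 2 for both chow groups, 2 interval-read genes for diet, 2 host genes against wild type and 1 for genotype. An estimated correlation left 0 interval-read lists against wild type, for genotype and against both chow groups. Without C57BL/6J 2 and ApoE-/- chow 1 together there were 0 circRNAs for diet, wild type and both chow groups, 3, 4, 4 and 5 host genes, 1, 6 and 9 interval-read genes for diet, wild type and genotype, 4, 1, 3 and 1 lists, and 0 shared.

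Values that reversed were these. Mean adipocyte log2 without C57BL/6J 1 was 0.15 against wild type (range with 1 library left out -0.69 to 0.15) and 0.012 against both chow groups (-0.41 to 0.012). Smooth muscle stood at -0.011 against wild type without C57BL/6J 2 (range -0.011 to 0.84) and at -0.015 without ApoE-/- chow 1 as well, and for genotype at -0.12 (range -0.12 to 0.73) and -0.31. With the count column the circRNA of Adrm1 was at log2 -0.51 for genotype and that of Peli2 at -0.13 against wild type. Without doubtful zeros, without the library it rested on, and without both libraries, in this order, junction reads of host Gigyf2 gave 1.19, 0.28 and 0.28 for diet and -1.74, -0.73 and -0.51 for genotype (ApoE-/- chow 1; ranges -4.98 to 0.28 and -0.73 to 4.45). Fitted values of host Ezh2 in the same order were 4.17, 4.44 and 4.58 against wild type and 1.27, 0.66 and 0.53 against both chow groups (C57BL/6J 2; ranges -8.29 to 4.44 and -7.70 to 0.66). They leave 0 reads in C57BL/6J against 7 and 0 in high-fat libraries, and the low ends, without high-fat 1, 0 in high-fat, so they give no size and no bound. Host Tlk1 without doubtful zeros gave 0.52 for diet and 0.24 against both chow groups, and Phf21a without C57BL/6J 1 gave 0.059 for genotype (range -4.09 to 0.059).

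With 1 library left out at a time, where a lone sample is assumed to vary like the other groups, circRNAs called ranged over 0–3, 0–2, 0–2 and 0–3, host genes over 0–1, 0–4, 0–1 and 0–5, interval-read genes over 0–5, 0–158, 0–65 and 1–103 (each highest value without C57BL/6J 1), interval-read lists over 0–4, 0–6, 1–2 and 0–5, junction-read lists at 0, the shared count over 0–2 and the detection ratio over 1.19–2.38. Such counts moved in 50 cases and stayed in 82; for single genes and lists 9 values reversed, 32 lost and 38 gained a call and 555 did neither.

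The replicate numbers of the labels were tried as a replicate block. Libraries with the same number did not deviate together: the correlation of their deviations across genes was -0.03 to 0.05 for circRNAs, -0.03 to 0.07 for host genes and -0.14 to 0.12 for interval reads, so the numbers do not pair the samples. With the block there were 1, 0, 0 and 1 circRNAs, 0, 0, 0 and 0 host genes, 0, 1, 0 and 3 interval-read genes, 0, 3, 1 and 3 lists and 0 shared circRNAs.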

Other observations

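All tests in this part were chosen only after the result was seen.

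Mitochondrial RNA took a larger share of the listed interval reads and of the junction reads in C57BL/6J than in ApoE-/- libraries. By interval reads the share was 1.77 and 2.07% in the C57BL/6J libraries and 0.981 to 1.14% in the 4 ApoE-/- libraries, a ratio of means of 1.85 (exact two-sided permutation p = 0.0667, the smallest that 15 splits can give). By junction reads it was 0.756 and 0.823% against 0.0686 to 0.273%, a ratio of 5.20 (exact two-sided permutation p = 0.0667). Junction reads of the mitochondrial chromosome numbered 219 and 28 in C57BL/6J, 35 and 45 in high-fat and 10 and 24 in ApoE-/- chow libraries. Scaled to library totals, the mitochondrial interval and junction reads of C57BL/6J 2 lie within the range of the ApoE-/- libraries. Its larger shares come with its low totals, 775094 interval and 3706 junction reads. Only C57BL/6J 1 stays above that range, so the shares do not establish a group difference in mitochondrial RNA. The library labelled ApoE-/- chow 1 had 1.05% by interval reads and 0.0686% by junction reads, within or below the range of the other ApoE-/- libraries. The design does not separate genotype from other differences between the groups' animals and preparations.

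Further genes were looked up for their known roles after their values were seen, and none passed in edgeR. Vcam1, a leukocyte adhesion molecule, stood at 42.3 ± 15.4 CPM of interval reads in high-fat, 21.7 ± 18.9 CPM in ApoE-/- chow and 11.2 ± 3.00 CPM in C57BL/6J aortae (SD, n = 2). Smtn, a cytoskeletal protein of contractile smooth muscle, stood at 342 ± 175, 266 ± 1.34 and 117 ± 80.3 CPM. Pcx, the pyruvate carboxylase of fat and liver, was at 25.6 ± 0.352, 62.0 ± 53.9 and 74.2 ± 56.1 CPM. Hba-a2 by the deposited symbol, an alpha globin whose copy Hba-a1 is nearly identical, was at 356 ± 356, 155 ± 128 and 112 ± 83.6 CPM. Its interval lies at chromosome 11, 32283958 to 32284375, and which of the copies lies there was not checked.

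Structural and ribosomal RNA intervals took uneven shares. Rpph1, Rmrp and Rn45s, the RNAs of RNase P, RNase MRP and the ribosomal precursor, made up 67.8 and 27.0% of interval reads in C57BL/6J 1 and 2, 56.5 and 44.4% in ApoE-/- chow and 56.3 and 58.6% in high-fat libraries.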
